A study of Mus musculus with 41 samples.

How the data were processed

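RNA was sequenced by the submitters from the brain tissue of male mice at least 10 weeks old labelled WT or KO for Lrp1, untreated or fed 0.3% cuprizone, and from OPC and macrophages sorted from spinal cord in EAE, per the labels' protocols, which give paired reads of 150 bases. Reads were checked with FastQC, trimmed with Trimmomatic and quantified with Salmon, per the submitters' processing notes, and the versions, settings, genome build and annotation release are not given in the sources used here. Each of the 41 libraries has a table of its own with a length, an effective length, a TPM value and an estimated read count for each transcript. The deposited estimated counts (expected counts per transcript, not normalized) were the values analysed here. The deposited TPM values and the deposited effective lengths, which have no unit class of their own, were used only to form the average transcript length of a gene in 1 alternative. The cuprizone files list 125570 transcripts and the EAE files 124031, which leaves 1043 genes without any transcript in the EAE files. Of the cuprizone transcripts 124980 (99.5%) were found in GENCODE M21, so gene coordinates are from that match, on GRCm38.

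The strain label names Lrp1 floxed mice with Olig1-Cre for WT and KO mice alike, and for the EAE mice the strain label names Pdgfra-CreERt2 while the treatment protocol names Olig1-Cre. Genotype was taken from the genotype label, which the sample titles repeat. The EAE libraries labelled WT carry the batch label 43479, which as a spreadsheet serial is 2019-01-14. The labels do not say that OPC and macrophage libraries with the same number came from the same animal, so the titles name libraries here. Groups were formed from the labels alone. Xist had at most 12 reads and Ddx3y at least 236 in each of the 41 libraries, which goes with the label of male mice. No 2 libraries held identical values.

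Transcript estimates were summed to 50600 genes and rounded to whole numbers. Each comparison was fitted in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, robust dispersion estimates, quasi-likelihood F test), with 1 mean per group, no covariate and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. The 16 libraries of the earlier cuprizone batch shared 1 fit, as did the 13 of the later batch, so no comparison crosses the batches. KO and WT were compared in OPC and in macrophages in separate fits of 6 libraries each, and the populations were compared in 1 fit of all 12. Interactions asked whether the KO and WT difference changed between weeks or between populations. CPM values used TMM scaling, and log2 CPM values a prior count of 0.5.

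A total of 35 gene lists for cell types, immune, lipid, stress and other processes was fixed before the data were examined, and up to 34 were tested per comparison where at least 5 members were measured. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and comparisons of one set of libraries, and again with an estimated correlation. The genes named in the text followed a rule that was also fixed then. For a comparison with calls it takes Lrp1, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 2 log2 CPM and no overlap between the groups (for interactions, without the overlap condition), and up to 4 members with the smallest p of each list described. For a comparison with 0 calls it takes Lrp1, the 5 genes with the smallest p and up to 3 members of a list. Unnamed gene models could be left out, and some genes that the rule takes are left out of the text for length, and some others are not reported here. Rpl34-ps1, Lyz1, and the pseudogenes and Gabra2 values set side by side across batches fall outside that rule and were chosen after their values were seen.

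Alternatives were median-of-ratios size factors in place of TMM, no low-count filter, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, an offset for average transcript length, only the groups compared or all 12 sorted libraries in the fit, the library number as a replicate block in the sorted cells, fry for the lists, and each library left out in turn. Added after seeing the data were the removal of the 2 libraries under 20 M (1e6) reads in the earlier batch and the mean of the homeostatic microglia list as a covariate at 5 and 5.5 weeks. The gene tests and list tests were tried on simulated counts with 200 changed genes, built from the means, spreads and library sizes of these libraries. The low-count filter, the transcript sums and the tests of splits and explanations were not part of it. Each gene was drawn independently, so shifts shared by many genes, as from tissue content or 1 deviant library, were not simulated. The false calls given here do not cover such shifts. For KO against WT, edgeR recovered 54% of genes changed by 1 log2 unit and 87% of those changed by 2 at 0 weeks (4 false calls among 19725 genes), 63% and 93% at 3 weeks (8 among 14931), 63% and 85% at 5 weeks (8 among 14931), and 76% and 92% at 5.5 weeks (8 among 19725). In sorted cells it recovered 19% and 60% in OPC (13 false calls among 15062 genes) and 6% and 55% in macrophages (6 among 16047), and for the interaction of genotype with population 2% and 25% (0 among 17816). DESeq2 made 65, 86 and 77 false calls in those 3 simulations. Replicate pairs differed by more than counting noise in all 53 cases (chi-square per degree of freedom 4 to 506.1), so SD and SE values stand for differences between animals and libraries. Correlations across samples, gene ontology terms and comparisons between batches were not analysed here.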

Results

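RNA sequencing of mouse tissue and sorted cells was used to compare mice labelled KO for Lrp1, a large endocytic receptor of the LDL receptor family, with mice labelled WT during toxic demyelination and during experimental autoimmune encephalomyelitis (EAE). Cuprizone, a copper chelator fed in chow, kills oligodendrocytes and strips myelin from the corpus callosum, while EAE is an immune attack on the spinal cord. The labels placed 16 tissue libraries in an earlier batch (0 weeks: 3 KO and 3 WT; 5.5 weeks: 5 KO and 5 WT) and 13 in a batch sequenced later the same year (3 weeks: 4 KO and 3 WT; 5 weeks: 3 KO and 3 WT). Another 12 libraries came from sorted oligodendrocyte progenitor cells (OPC) and macrophages of the EAE spinal cord, with 3 KO and 3 WT libraries of each. The labels call the tissue whole cortex, while their extract protocol describes dissected corpus callosum from slices of 3 mm for untreated and 2 mm for treated mice. Week numbers are tagged as weeks after demyelination and described as weeks of cuprizone, while the protocol gives 5 weeks of feeding for every treated group, the 3 week mice included, so only the number is used here. The 0 week mice had no cuprizone and shared a batch with the 5.5 week groups. All 0 week libraries came from slices of 3 mm and all 5.5 week libraries from slices of 2 mm, so an effect of cuprizone and one of the piece taken were not separated between these weeks. No untreated group shared a batch with the 3 and 5 week mice.

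Estimated reads in the 0 week libraries, in M (1e6 reads), came to 34.13 (ko_0wk_466), 15.14 (ko_0wk_467) and 29.77 M (ko_0wk_468) in KO and 27.06 (wt_0wk_852), 15.88 (wt_0wk_853) and 27.69 M (wt_0wk_854) in WT. At 5.5 weeks they came to 27.46 (ko_5_5wk_361), 26.4 (ko_5_5wk_383), 26.21 (ko_5_5wk_384), 26.26 (ko_5_5wk_385) and 38.6 M (ko_5_5wk_386) in KO, and to 34.23 (wt_5_5wk_638), 27.69 (wt_5_5wk_640), 29.64 (wt_5_5wk_641), 29.55 (wt_5_5wk_643) and 36.27 M (wt_5_5wk_644) in WT. The later batch was shallower, with 6.65 (ko_3wk_321), 3.89 (ko_3wk_323), 6.05 (ko_3wk_324) and 3.56 M (ko_3wk_326) in KO and 3.34 (wt_3wk_209), 4.04 (wt_3wk_210) and 4.16 M (wt_3wk_211) in WT at 3 weeks. At 5 weeks the KO libraries held 9.57 (ko_5wk_320), 7.33 (ko_5wk_327) and 4.29 M (ko_5wk_298) and the WT libraries 3.91 (wt_5wk_212), 4.87 (wt_5wk_213) and 4.04 M reads (wt_5wk_214). WT macrophage libraries held 34.7 (wt_402_Mac), 38.78 (wt_802_Mac) and 37.94 M (wt_806_Mac), and KO macrophage libraries 30 (ko_47_Mac), 43.87 (ko_48_Mac) and 27.63 M (ko_49_Mac). WT OPC libraries held 11.97 (wt_402_OPC), 26.02 (wt_802_OPC) and 23.81 M (wt_806_OPC), and KO OPC libraries 20.69 (ko_47_OPC), 25.61 (ko_48_OPC) and 20.77 M (ko_49_OPC). Between 16141 and 19664 genes had at least 10 reads in the earlier cuprizone batch, between 13550 and 15791 in the later one, and between 13619 and 16269 in the sorted cells. In the text below, levels are CPM, counts per M reads after scaling of the libraries, as mean ± SD over libraries, and fold changes are log2 values ± SE from edgeR with adjusted p.

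Lrp1 (ENSMUSG00000040249, GRCm38 chromosome 10, 127538161 to 127621148, minus strand), the gene targeted in the KO mice, was measured first as a check on the labels. Its level in KO tissue was 306.1 ± 95.13 against 509.7, 452.6 and 435.8 CPM in WT at 0 weeks (n = 3 and 3; log2 −0.61 ± 0.55, adjusted p = 0.972), a difference that did not pass. Lrp1 fell in KO tissue at 3 weeks, to 189.8 ± 32.53 from 446.9 ± 34.93 CPM (n = 4 and 3; −1.23 ± 0.18, adjusted p = 0.0171). At 5 weeks it fell to 173 ± 34.12 from 640.3 ± 158.7 CPM (n = 3 and 3; −1.89 ± 0.20, adjusted p = 0.00148). At 5.5 weeks it fell to 370.5 ± 286.6 from 1319 ± 604.1 CPM (n = 5 and 5; −1.83 ± 0.43, adjusted p = 0.00758). The library labelled ko_5_5wk_384, at 841.5 CPM, lay inside the WT range of 806.4 to 2353 CPM. In sorted macrophages Lrp1 was 444 ± 43.65 CPM in KO and 1117 ± 136.5 CPM in WT (n = 3 and 3; −1.33 ± 0.17, adjusted p = 0.187), with no overlap between the groups. In sorted OPC the libraries labelled ko_47_OPC and ko_48_OPC held 14.73 and 18.78 CPM, while the library labelled ko_49_OPC held 159.4 CPM, next to 165.3, 213.9 and 198 CPM in WT (−1.58 ± 1.1, adjusted p = 0.63). Without the library labelled ko_49_OPC the OPC difference became −3.52 ± 0.20 (adjusted p = 0.000313), and without ko_48_Mac the macrophage difference passed at −1.27 (adjusted p = 0.00238). The 3 week call ended without ko_3wk_323 (adjusted p = 0.0607), ko_3wk_326 (0.0913), wt_3wk_209 (0.0694), wt_3wk_210 (0.121) or wt_3wk_211 (0.0583), and under a transcript length offset (0.194). Transcript sums cover the whole gene, so reads outside a deleted part of Lrp1 count as well. The extent of the deletion is not given in the sources. By Rpl34-ps1, ko_5_5wk_384 (55.53 CPM) and ko_49_OPC (24.35 CPM) stood with KO (WT at most 0.3073 CPM).

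**Figure D1:**
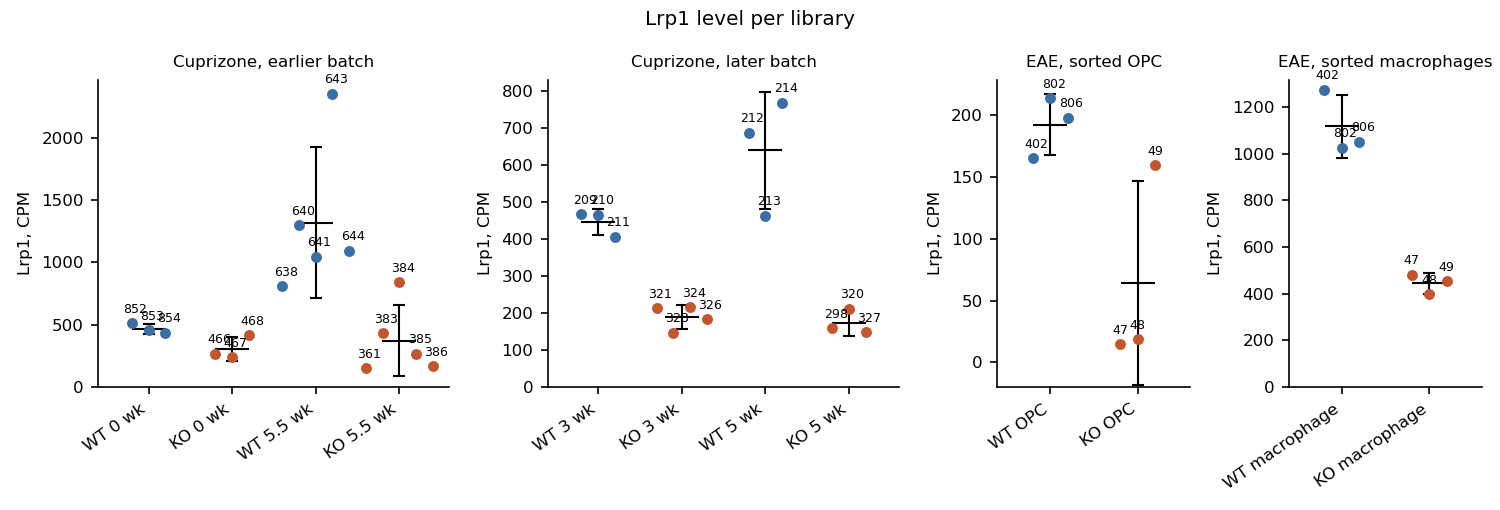
Lrp1 level (CPM, linear axis) in each library of both cuprizone batches, the sorted OPC and the sorted macrophages, WT in blue and KO in orange, with library numbers beside the points and black bars for mean ± SD. The library ko_49_OPC sits at 159.4 CPM, far above the 14.73 and 18.78 CPM of the other OPC labelled KO. The library ko_5_5wk_384 sits at 841.5 CPM inside the WT range.

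In tissue before cuprizone, KO and WT mice were compared, with 3 libraries each. Agt, the precursor of angiotensin made by astrocytes of deeper brain regions, rose in KO to 44.49 ± 6.271 from 5.923 ± 0.6695 CPM (n = 3 and 3; log2 2.90 ± 0.30, adjusted p = 0.000199). Slc6a11, a GABA transporter of astrocytes, rose to 328.9 ± 6.963 from 177.2 ± 13.6 CPM (0.89 ± 0.16, adjusted p = 0.0275). Asic4, an acid-sensing channel subunit, rose to 24.34 ± 2.723 from 8.052 ± 1.668 CPM (1.60 ± 0.18, adjusted p = 0.000349). Transcription factors rose as well, namely Tal1 (2.94 ± 0.55, adjusted p = 0.0317), Pbx3 (1.14 ± 0.19, adjusted p = 0.0134) and Tcf7l2 (1.98 ± 0.34, adjusted p = 0.0171), the last of which marks thalamic neurons and newly formed oligodendrocytes. Slco1a4, a transporter of brain endothelium, fell to 27.98 ± 1.508 from 44.88 ± 4.599 CPM (−0.68 ± 0.13, adjusted p = 0.0319), and Snapc1 fell by 0.92 ± 0.16 (adjusted p = 0.0171). Every KO library lay outside the WT range for each of these genes, which the naming rule asks of the largest rises and falls and which adds no evidence for them. Transcription factors of midbrain, thalamus and hindbrain, chosen after their values were seen, were near absent in WT: Barhl1 (3.65 ± 0.7812 against 0.0482 ± 0.05569 CPM), Gata3 (4.079 ± 0.8003 against 0.07894 ± 0.05548), Irx2 (3.113 ± 0.3488 against 0.01213 ± 0.02101) and Shox2 (7.21 ± 0.8079 against 0.2555 ± 0.288). All passed (adjusted p = 0.000139 for Barhl1, Gata3 and Irx2 and 0.000349 for Shox2). Ttr, a choroid plexus product, ranged from 985.5 to 1505 CPM in KO and from 31.26 to 765.1 CPM in WT (1.58 ± 1.03, adjusted p = 0.924). Whether the pieces of tissue dissected differed between the groups is not given in the sources used here, so that and genotype were not separated. In the later batch these factors varied within a genotype. At 3 weeks ko_3wk_321 held Barhl1 at 10.7, Gata3 at 17.83, Irx2 at 14.86 and Shox2 at 34.03 CPM, against at most 0.4855, 1.427, 0.9513 and 0.548 CPM in the other KO libraries. Irx2 and Shox2 were at 10.91 and 7.272 CPM in wt_3wk_210 and 10.98 and 17.84 CPM in wt_3wk_211, against 0.597 and 0.2985 CPM in wt_3wk_209. Of 19725 genes tested, 59 passed, with 44 higher and 15 lower in KO. Of the 30 genes of mature oligodendrocytes and myelin 0 passed over all genes and 0 adjusted over the list alone, with 29 of 30 lower (median −0.33) and a camera adjusted p of 0.00341 (adjusted p = 0.71 with an estimated correlation). Of 18 endothelial and mural genes 0 rose and 1 fell (0 and 2 adjusted over the list alone), with a median of −0.26 and a camera adjusted p of 2.57e-05 (adjusted p = 0.57 with an estimated correlation). The 15 ependyma and choroid plexus genes had a median of 0.64 with 0 called either way (camera adjusted p = 0.000258, adjusted p = 0.573 with an estimated correlation). The count was 37 without ko_0wk_466 or wt_0wk_854, 38 without ko_0wk_468 and 33 without ko_0wk_467 and wt_0wk_853, the shallowest pair. Agt, Asic4, Barhl1, Gata3, Irx2 and Shox2 passed in all 6 fits that left out 1 library, Pbx3 in 3, Snapc1 in 2, Tcf7l2 in 1, and Tal1, Slc6a11 and Slco1a4 in 0.

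At 3 weeks few genes separated KO from WT tissue. Of 14931 genes 12 passed, 2 higher and 10 lower in KO, among them Lrp1 and the meiotic cohesin gene Rec8. Most of the others were pseudogenes, such as Gm13456, at 1.374 ± 0.6692 CPM in KO and 35.03 ± 1.958 CPM in WT (n = 4 and 3; −4.63 ± 0.24, adjusted p = 4.08e-07). An antisense or near-identical copy can share reads with such models. Of 33 genes induced by interferon 0 passed over all genes and 0 adjusted over the list alone, with a median of −0.64. As a list they fell relative to other genes by camera (adjusted p = 3.39e-15, adjusted p = 0.357 with an estimated correlation). Its member Oas1a, a sensor of viral RNA (−1.81 ± 0.46, adjusted p = 0.649), did not pass. Of the 30 myelin genes 0 passed by either adjustment (median −0.27, camera adjusted p = 6.59e-05, adjusted p = 0.545 with an estimated correlation). The count was 7 without wt_3wk_211.

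At 5 weeks KO tissue held less microglial transcript than WT tissue. Tmem119, a marker of resident microglia, fell to 35.44 ± 10.72 from 222.7 ± 113.8 CPM (n = 3 and 3; −2.63 ± 0.38, adjusted p = 0.0106). Siglech fell to 26.52 ± 5.208 from 140.5 ± 69.76 CPM (−2.38 ± 0.29, adjusted p = 0.00422), and the purinergic receptor P2ry12 to 64.99 ± 4.151 from 242.4 ± 111.3 CPM (−1.89 ± 0.26, adjusted p = 0.00846). Of 20 homeostatic microglia genes 0 rose and 17 fell (0 and 19 adjusted over the list alone; camera adjusted p = 2.09e-14, adjusted p = 0.329 with an estimated correlation). Of 30 disease-associated microglia genes 0 rose and 11 fell (0 and 18 adjusted over the list alone). Among them were the cystatin Cst7 (116.9 ± 34.9 against 467.6 ± 188.1 CPM, −1.99 ± 0.38, adjusted p = 0.0194) and the lipid receptor Trem2 (−1.38 ± 0.29, adjusted p = 0.0209). That list had a camera adjusted p of 7.43e-09 (adjusted p = 0.42 with an estimated correlation). Genes that load and carry MHC class I peptides fell in 19 of 24 cases with 0 rises (23 falls adjusted over the list alone; camera adjusted p = 3.39e-15, adjusted p = 0.329 with an estimated correlation). Examples were H2-K1 (193.2 ± 62.51 against 625.8 ± 246.1 CPM, −1.69 ± 0.28, adjusted p = 0.015) and H2-Q7 (−2.49 ± 0.39, adjusted p = 0.0118), related genes between which reads can be shared. Of 28 lysosomal genes 0 rose and 19 fell (1 and 24 adjusted over the list alone), including the hexosaminidase subunit Hexa (−1.32 ± 0.26), with a camera adjusted p of 6.96e-12 (adjusted p = 0.357 with an estimated correlation).

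Genes of other kinds were called at 5 weeks as well. Of 28 ribosomal protein genes 0 rose and 24 fell (27 adjusted over the list alone), such as Rplp0, at 427.2 ± 23.59 against 813.9 ± 251.8 CPM (−0.93 ± 0.18, adjusted p = 0.0194). Their camera adjusted p was 2.99e-16 (adjusted p = 0.35 with an estimated correlation). The interferon list had 0 rises and 5 falls among 33 genes (17 falls adjusted over the list alone; camera adjusted p = 1.22e-09, adjusted p = 0.42 with an estimated correlation), led by Oas1a (−1.83 ± 0.37, adjusted p = 0.0194). Ccl12, a chemokine that draws monocytes, fell to 4.752 ± 1.179 from 40.99 ± 27.16 CPM (−3.07 ± 0.52, adjusted p = 0.0153). Of 24 neuronal genes 2 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 1.7e-06, adjusted p = 0.357 with an estimated correlation). Syt1, the calcium sensor of synaptic vesicles, rose to 1036 ± 29.91 from 679.5 ± 114.4 CPM (0.61 ± 0.15, adjusted p = 0.0326). The GABA receptor subunit Gabra2 rose to 153.1 ± 40.43 from 42.51 ± 1.569 CPM (1.85 ± 0.41, adjusted p = 0.0251). The haemoglobin gene Hbb-bs, a marker of blood left in the tissue, rose by 1.92 ± 0.38 (adjusted p = 0.0194). Of the 30 myelin genes 0 passed by either adjustment (median 0.13, camera adjusted p = 0.15). In all, 922 of 14931 genes passed, 163 higher and 759 lower in KO. This count rested on single libraries, since it was 9 without ko_5wk_327, 16 without ko_5wk_298, 23 without wt_5wk_212, 95 without wt_5wk_214, 345 without ko_5wk_320 and 2256 without wt_5wk_213. It was 13 with only the 6 libraries of this week in the fit and 7 with the microglia list mean as a covariate. Siglech passed in all 6 fits that left out 1 library, P2ry12 in 4, Tmem119, H2-K1, H2-Q7, Ccl12 and Rplp0 in 3, Cst7, Trem2, Hexa, Oas1a and Hbb-bs in 2, and Syt1 and Gabra2 in 1.

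At 5.5 weeks the microglial difference was present in the other, deeper batch as well. All 20 homeostatic microglia genes fell in KO (20 adjusted over the list alone; camera adjusted p = 7.68e-13, adjusted p = 0.57 with an estimated correlation). Tmem119 fell to 28.06 ± 17.1 from 241.3 ± 155.9 CPM (n = 5 and 5; −3.11 ± 0.42, adjusted p = 0.0012). P2ry12 fell to 37.18 ± 17.83 from 183.2 ± 77.09 CPM (−2.30 ± 0.32, adjusted p = 0.00143), and Siglech by 2.58 ± 0.31 (adjusted p = 0.00052). Of the 30 disease-associated microglia genes 0 rose and 23 fell (25 adjusted over the list alone; camera adjusted p = 3.79e-10, adjusted p = 0.573 with an estimated correlation). Further large falls were those of Gpr84, a receptor induced on activated microglia (6.142 ± 6.334 against 68.2 ± 45.99 CPM, −3.49 ± 0.61, adjusted p = 0.00352), Fcrls (230.8 ± 266.5 against 1993 ± 1316 CPM, −3.11 ± 0.67, adjusted p = 0.00549) and the cholesterol 25-hydroxylase Ch25h (−3.39 ± 0.70, adjusted p = 0.00501). All 24 MHC class I genes fell (24 adjusted over the list alone; camera adjusted p = 2.61e-13, adjusted p = 0.57 with an estimated correlation), including H2-K1, at 177.2 ± 92.81 against 700.6 ± 213.9 CPM (−1.98 ± 0.29, adjusted p = 0.00204). Of 14 MHC class II genes 0 rose and 9 fell (9 adjusted over the list alone; camera adjusted p = 0.00194, adjusted p = 0.566 with an estimated correlation). Of 34 interferon genes 0 rose and 27 fell (28 adjusted over the list alone; camera adjusted p = 6.51e-10, adjusted p = 0.573 with an estimated correlation), led by Isg15 (−1.74 ± 0.28, adjusted p = 0.00286). All 24 proliferation genes fell (24 adjusted over the list alone), among them the cell cycle marker Mki67 (6.176 ± 5.785 against 53.66 ± 37.91 CPM, −3.13 ± 0.55) and the ribonucleotide reductase subunit Rrm2 (−2.72 ± 0.42), with a camera adjusted p of 1.64e-14 (adjusted p = 0.57 with an estimated correlation). Of 28 lysosomal genes 1 rose and 25 fell (1 and 25 adjusted over the list alone; camera adjusted p = 2.78e-10, adjusted p = 0.573 with an estimated correlation). Glb1, a lysosomal galactosidase, fell by 1.96 ± 0.35, while Atp6v1a, a proton pump subunit that neurons also use, was the one that rose (0.55 ± 0.11). All 28 ribosomal protein genes fell (28 adjusted over the list alone; camera adjusted p = 1.51e-14, adjusted p = 0.57 with an estimated correlation).

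Neuronal, cholesterol synthesis and myelin lists were also examined at 5.5 weeks. Of 24 neuronal genes 18 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 4.66e-07, adjusted p = 0.574 with an estimated correlation). The vesicular glutamate transporter Slc17a7 rose to 845.4 ± 191.5 from 486.6 ± 119.7 CPM (0.80 ± 0.20, adjusted p = 0.00857) and the GABA synthesis enzyme Gad1 to 243.9 ± 78.73 from 118.2 ± 38.41 CPM (1.05 ± 0.26, adjusted p = 0.00853). Reln rose to 43.91 ± 15.42 from 15.74 ± 5.695 CPM (1.48 ± 0.29, adjusted p = 0.00427) and Gabra2 to 62.42 ± 26.04 from 11.07 ± 3.438 CPM (2.49 ± 0.29, adjusted p = 0.000476). Gabra2 was also at 67.36 ± 0.5315 CPM in KO and 31.11 ± 2.385 CPM in WT before cuprizone. Of 22 cholesterol synthesis genes 10 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0021, adjusted p = 0.627 with an estimated correlation), such as Hmgcs1 (0.77 ± 0.18) and Cyp51 (0.59 ± 0.15). Myelin genes were mixed, with 5 rises and 1 fall among 30 (0 and 1 adjusted over the list alone), a median of 0.67 and a camera adjusted p of 0.00053 (adjusted p = 0.704 with an estimated correlation). Aspa, an enzyme of oligodendrocytes, rose by 0.97 ± 0.30 (adjusted p = 0.0198), while the iron carrier Trf fell to 753.1 ± 321.1 from 1719 ± 236.5 CPM (−1.19 ± 0.23, adjusted p = 0.00459). The homeostatic microglia list mean was 6.76 ± 0.96 log2 CPM in KO and 9.13 ± 0.54 in WT, and mitochondrial reads made up 6.178 to 9.332% of KO and 4.277 to 5.868% of WT libraries. Of 19725 genes 7900 passed, 3680 higher and 4220 lower (2269 and 5525 with all KO levels lowered by 0.1 log2 units, 5270 and 3202 with them raised by 0.1, 3183 and 2912 without wt_5_5wk_643), and of the 2124 called genes with more than a 2-fold change 443 were higher and 1681 lower. The count was 5234 without ko_5_5wk_386 and 16 with the microglia list mean as a covariate, a setting chosen after seeing the data. Under that covariate Lrp1 was at 0.26 ± 0.34 (adjusted p = 0.92), and Fcrls (0.1), Slc17a7 (−0.21), Gad1 (−0.29) and Hmgcs1 (−0.04) turned sign.

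**Figure D2:**
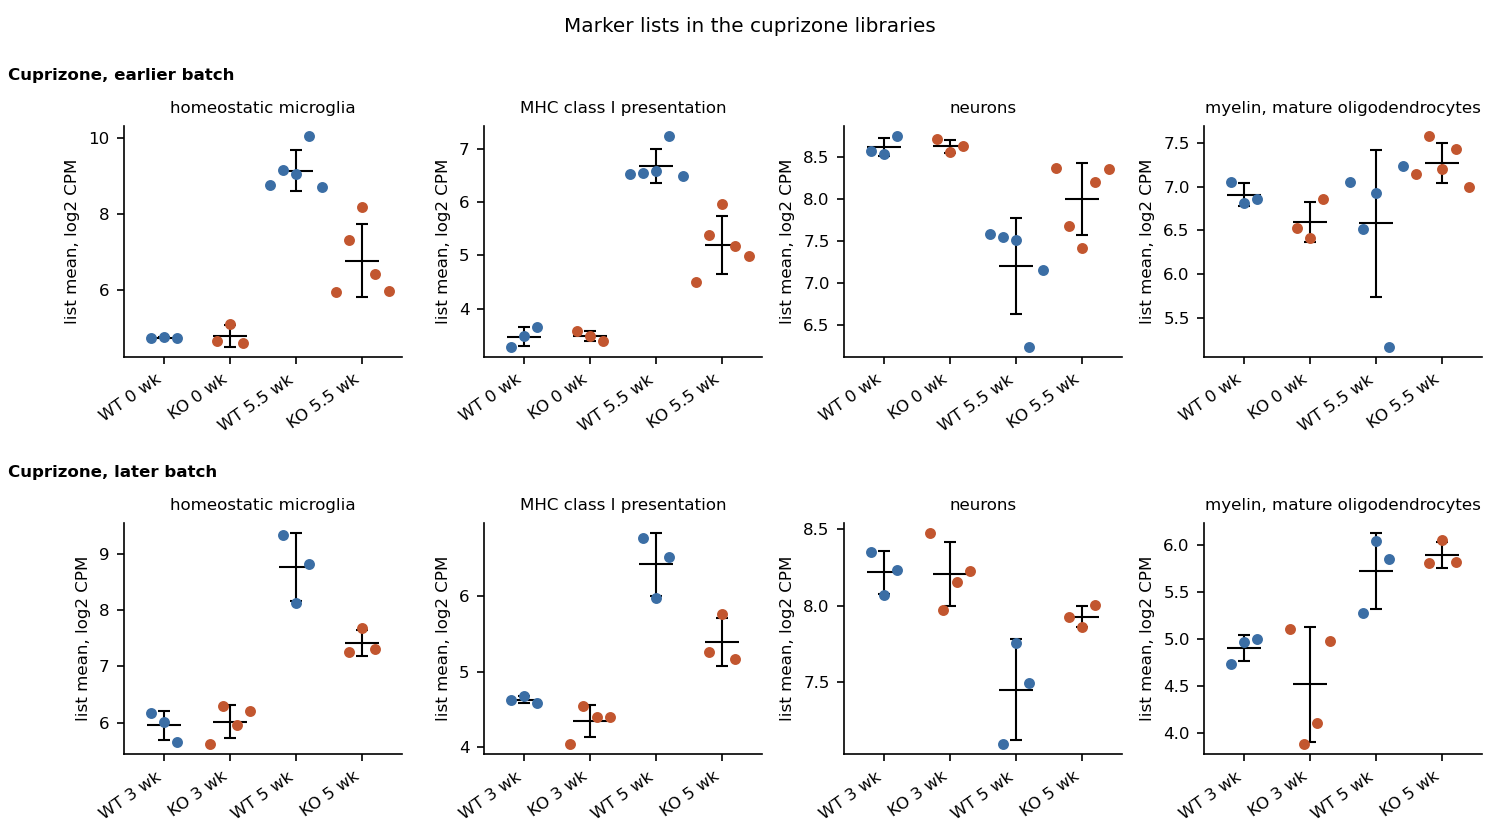
Mean log2 CPM of the homeostatic microglia, MHC class I, neuronal and myelin lists in each cuprizone library, by week and genotype (WT blue, KO orange), with black bars for mean ± SD and the batches in separate panels. At 5.5 weeks the microglia list mean was 6.76 ± 0.96 in KO and 9.13 ± 0.54 in WT, while before cuprizone it was 4.78 ± 0.28 and 4.74 ± 0.02.

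Within WT mice, 5.5 week tissue was compared with untreated tissue. Transcripts near absent from untreated tissue were among those that rose, with the activated microglia genes Cst7 at 963 ± 605.6 CPM after 0.226 ± 0.05398 and Itgax at 327.8 ± 54.73 after 0.1669 ± 0.1599, and Lcn2, of reactive astrocytes, at 173.5 ± 43.71 after 0.322 ± 0.4334 CPM (n = 5 and 3). Lysozyme (Lyz2) rose to 1289 ± 271.2 from 8.127 ± 3.177 CPM (7.32 ± 0.51, adjusted p = 2.28e-06). The complement gene C1qa rose to 3245 ± 1579 from 39.87 ± 2.889 CPM (6.35 ± 0.74), and the MHC class II chain H2-Ab1 to 40.42 ± 3.748 from 1.74 ± 1.746 CPM (4.65 ± 0.53). All 20 homeostatic and all 30 disease-associated microglia genes rose, as did all 14 MHC class II genes (also when adjusted over the list alone). Their camera adjusted p were 4.17e-10, 1.28e-14 and 1.34e-06, against adjusted p = 0.573, 0.57 and 0.334 with an estimated correlation. All 21 reactive astrocyte genes rose (21 adjusted over the list alone), such as the complement gene C4b (540.2 ± 125.9 against 27.89 ± 3.377 CPM, 4.28 ± 0.23, adjusted p = 1.87e-07) and the filament Vim (1051 ± 84.16 against 36.92 ± 5.025 CPM, 4.83 ± 0.36). Their camera adjusted p was 5.15e-12 (adjusted p = 0.566 with an estimated correlation). All 24 proliferation genes rose (24 adjusted over the list alone; camera adjusted p = 8.68e-09, adjusted p = 0.573 with an estimated correlation), among them the replication helicase subunit Mcm3 (3.61 ± 0.48).

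Oligodendrocyte lineage genes rose with them in WT, with 15 of 17 newly formed oligodendrocyte genes and 16 of 24 OPC genes higher and 0 and 3 lower. The counts were the same adjusted over each list alone, and the camera adjusted p were 0.000535 and 0.00773 (adjusted p = 0.627 with an estimated correlation for both). Examples were the calcium channel Itpr2 (2.27 ± 0.30, adjusted p = 3.21e-05) and the proteoglycan Cspg4 (3.45 ± 0.52, adjusted p = 7.19e-05). Of 30 myelin genes 4 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.248). All 24 neuronal genes fell (24 adjusted over the list alone; camera adjusted p = 2.58e-07, adjusted p = 0.574 with an estimated correlation), including the synaptic Snap25, to 825.4 ± 265.4 from 2798 ± 762.2 CPM (−1.76 ± 0.29), Gad1 (−1.61 ± 0.29) and the serotonin receptor Htr2a (−2.38 ± 0.30). Of 22 cholesterol synthesis genes 1 rose and 17 fell, also adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.573 with an estimated correlation), for instance Insig1, a regulator of sterol synthesis (25.71 ± 1.425 against 77.28 ± 12.63 CPM, −1.59 ± 0.14). Lrp1 itself rose in WT (1.5 ± 0.52, adjusted p = 0.0195), though that call ended without wt_0wk_853 (adjusted p = 0.0563), wt_0wk_854 (0.0607) or wt_5_5wk_643 (0.0513). Mitochondrial reads made up 7.359 to 10.058% of WT libraries at 0 weeks and 4.277 to 5.868% at 5.5 weeks, without overlap. In all, 12506 of 19725 genes passed, 6424 higher and 6082 lower (5968 and 6240 without wt_5_5wk_643).

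Within KO mice, 5.5 week tissue was likewise compared with untreated tissue. Lyz2 rose to 546.6 ± 234.3 from 6.543 ± 2.764 CPM (n = 5 and 3; 6.39 ± 0.49, adjusted p = 9.17e-06). Gpnmb, a marker of lipid-laden phagocytes, rose to 339.2 ± 392.9 from 2.914 ± 0.1754 CPM (6.85 ± 1.15, adjusted p = 0.000985), while Cst7 reached 116.4 ± 176.7 from 0.2201 ± 0.1673 CPM. All 30 disease-associated and 15 of 20 homeostatic microglia genes rose with 0 falls (30 and 16 adjusted over the list alone). Their camera adjusted p were 2.01e-19 and 1.68e-07 (adjusted p = 0.566 and 0.573 with an estimated correlation). Of 21 reactive astrocyte genes 20 rose (21 adjusted over the list alone; camera adjusted p = 5.9e-19, adjusted p = 0.512 with an estimated correlation), including C4b, at 519.8 ± 82.09 against 34.45 ± 5.44 CPM (3.91 ± 0.22), and Vim (3.85 ± 0.34). Newly formed oligodendrocyte genes rose in 14 of 17 cases with 0 falls (14 adjusted over the list alone; camera adjusted p = 2.97e-07, adjusted p = 0.573 with an estimated correlation), led by Gpr17, a receptor of cells committed to differentiate (322.8 ± 171.9 against 48.64 ± 3.983 CPM, 2.73 ± 0.44), and Itpr2 (2.00 ± 0.30). Of 24 OPC genes 17 rose and 0 fell (18 and 1 adjusted over the list alone; camera adjusted p = 2.13e-05, adjusted p = 0.573 with an estimated correlation), such as the proteoglycan Vcan (1.52 ± 0.28). Of 30 myelin genes 13 rose and 5 fell (17 and 6 adjusted over the list alone; camera adjusted p = 0.0346, adjusted p = 0.773 with an estimated correlation). Of 24 proliferation genes 5 rose (5 adjusted over the list alone; camera adjusted p = 0.00254, adjusted p = 0.704 with an estimated correlation), with Mcm3 at 1.62 ± 0.44 (adjusted p = 0.017). Of 24 neuronal genes 2 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 5.76e-05, adjusted p = 0.651 with an estimated correlation). The thalamic glutamate transporter Slc17a6 fell to 15.98 ± 5.378 from 73.23 ± 7.199 CPM (−2.19 ± 0.40), and Gad2 fell by 0.92 ± 0.32 (adjusted p = 0.0491). The Gad2 call passed in 2 of 8 fits that left out 1 library, those without ko_5_5wk_361 or ko_5_5wk_386, and that of Mcm3 in 6, ending without ko_0wk_466 or ko_0wk_468. Ttr, the main product of choroid plexus, fell to 25.98 ± 15.91 from 1200 ± 271.3 CPM (−5.53 ± 0.99, adjusted p = 0.00144). The falls of Slc17a6 and Ttr went with the thinner slice as well as with cuprizone. Of 19725 genes 4941 passed, 3214 higher and 1727 lower. The count was 2669 without ko_0wk_466, 2613 without ko_0wk_467, 2854 without ko_0wk_468 and 3289 without ko_5_5wk_383.

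Whether the 5.5 week response differed between genotypes was tested as an interaction, in which 21 genes passed, 2 higher and 19 lower in KO. Agt had risen in KO before cuprizone and fell there to 8.008 ± 1.023 CPM by 5.5 weeks (−2.47 ± 0.25, adjusted p = 3.35e-05), a fall that also went with the thinner slice, which gave an interaction of −2.56 ± 0.37 (adjusted p = 0.0146). Tal1 (−4.71 ± 0.67, adjusted p = 0.0146), Pbx3 (−1.71 ± 0.24, adjusted p = 0.0145), Zfhx3 (−2.55 ± 0.45, adjusted p = 0.0456), Nfatc2 (−1.78 ± 0.29, adjusted p = 0.0289) and Cnbd2 (−1.37 ± 0.22, adjusted p = 0.0281) were lower. Far1 (0.63 ± 0.10, adjusted p = 0.0231) and Uri1 (0.52 ± 0.09, adjusted p = 0.0496) were higher. The regional transcription factors raised in KO before cuprizone were at 0.06197 (Barhl1), 0.2158 (Gata3), 0.0575 (Irx2) and 0.1102 CPM (Shox2) on average in KO at 5.5 weeks. Barhl1 (−6.36 ± 0.87, adjusted p = 0.0142) and Gata3 (−4.55 ± 0.75, adjusted p = 0.0289) passed the interaction, and Irx2 (adjusted p = 0.164) and Shox2 (adjusted p = 0.181) did not. For the microglial lists the interaction called 0 genes over all genes tested, but 18 of 20 homeostatic genes were lower when adjusted over the list alone (median −2.30, camera adjusted p = 1.38e-11, adjusted p = 0.573 with an estimated correlation). The same held for 19 of 24 MHC class I genes, 22 of 24 proliferation genes and 27 of 28 ribosomal protein genes (camera adjusted p = 1.6e-11, 2.57e-12 and 1.51e-14, adjusted p = 0.57 with an estimated correlation for each). The 30 myelin genes had a median of 1.00 with 0 called by either adjustment (camera adjusted p = 1.77e-05, adjusted p = 0.627 with an estimated correlation). The number of genes called rested on single libraries, with 3435 without ko_5_5wk_384, 591 without wt_5_5wk_643, 69 without wt_0wk_852 and 6 without wt_0wk_854. It was also 7 without ko_0wk_467, wt_0wk_853, ko_5_5wk_383 or ko_5_5wk_385, 9 without ko_0wk_466 or ko_5_5wk_386, 10 without wt_5_5wk_640, 12 without ko_0wk_468, and 1 without ko_0wk_467 and wt_0wk_853 together. DESeq2 called 2460 genes and limma voom 7270. Pbx3 and Barhl1 passed in all 16 fits that left out 1 library, Tal1 in 14, Agt in 13, and Far1, Nfatc2, Cnbd2, Zfhx3, Gata3 and Uri1 in 7, 6, 6, 5, 5 and 3.

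In the later batch, 5 weeks was compared with 3 weeks. In WT, Apoe rose to 16590 ± 3629 from 2124 ± 328.9 CPM (n = 3 and 3; 2.97 ± 0.21, adjusted p = 7.54e-06) and the neighbouring apolipoprotein gene Apoc1 to 56.98 ± 18.25 from 2.384 ± 1.283 CPM (4.60 ± 0.34). Cst7 rose to 467.6 ± 188.1 from 19.63 ± 5.757 CPM (4.58 ± 0.44) and Trem2 by 3.83 ± 0.32 (adjusted p = 1.72e-05). All 30 disease-associated and all 20 homeostatic microglia genes rose, also adjusted over the list alone (camera adjusted p = 6.94e-20 and 2.99e-16, adjusted p = 0.329 with an estimated correlation for both). Of 30 myelin genes 15 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 0.000257, adjusted p = 0.591 with an estimated correlation). Mbp, a main protein of compact myelin, rose to 1046 ± 220.8 from 341.2 ± 13.46 CPM (1.62 ± 0.27), and Ugt8a, which makes galactolipids, by 1.64 ± 0.21. Of 16 newly formed oligodendrocyte genes 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.000699, adjusted p = 0.329 with an estimated correlation), among them Enpp6 (34.69 ± 7.115 against 9.199 ± 1.253 CPM, 1.91 ± 0.20) and Gpr17 (1.34 ± 0.23). Of 24 neuronal genes 14 fell and 0 rose (18 and 0 adjusted over the list alone; camera adjusted p = 4.1e-07, adjusted p = 0.357 with an estimated correlation), with Syt1 at −0.91 ± 0.15 and Gad1 at −1.02 ± 0.20. Lrp1 did not pass (0.52 ± 0.20, adjusted p = 0.0608). Mitochondrial reads made up 7.974 to 10.769% of WT libraries at 3 weeks and 11.083 to 12.615% at 5 weeks, without overlap. Of 14931 genes 4611 passed, 2658 higher and 1953 lower, and without wt_5wk_212 there were 3018.

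Within KO mice, 5 weeks was likewise compared with 3 weeks. Apoe rose to 14570 ± 729.8 from 2276 ± 476.1 CPM (n = 3 and 4; 2.68 ± 0.19, adjusted p = 1.16e-05), Apoc1 by 3.90 ± 0.30 and Trem2 by 2.50 ± 0.28. Lyz2 rose to 542.9 ± 85.57 from 59.17 ± 44.68 CPM (3.23 ± 0.52, adjusted p = 0.00308) and the MHC class II chaperone Cd74 to 103.2 ± 17.35 from 15.39 ± 6.551 CPM (2.78 ± 0.32). Of 30 disease-associated microglia genes 29 rose, of 20 homeostatic ones 14 and of 11 MHC class II genes 9, with 0 falls in each (30, 17 and 10 adjusted over the list alone). Their camera adjusted p were 1.45e-24, 3.38e-14 and 2.76e-11 (adjusted p = 0.329, 0.329 and 0.325 with an estimated correlation). Of 30 myelin genes 15 rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 8.83e-15, adjusted p = 0.329 with an estimated correlation), such as the tight junction gene Cldn11 (160.7 ± 21.4 against 37.53 ± 10.54 CPM, 2.11 ± 0.19) and Ugt8a (1.96 ± 0.19). Of 16 newly formed oligodendrocyte genes 11 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 4.08e-11, adjusted p = 0.0777 with an estimated correlation), led by Enpp6 (52.53 ± 4.993 against 8.544 ± 1.658 CPM, 2.64 ± 0.17), with Gpr17 at 1.42 ± 0.20. Of 21 immediate early genes, which neuronal activity and tissue handling induce, 0 rose and 5 fell (2 and 12 adjusted over the list alone; camera adjusted p = 0.000535, adjusted p = 0.325 with an estimated correlation), including Arc (−1.72 ± 0.43, adjusted p = 0.0287) and Fos (−0.68 ± 0.18, adjusted p = 0.0326). Each passed in 2 of 7 fits that left out 1 library. Nes, a filament of progenitors and reactive astrocytes, fell by 1.70 ± 0.33. Of 14931 genes 1461 passed, 1086 higher and 375 lower, and the count was 593 without ko_5wk_320, 680 without ko_5wk_298, 876 without ko_5wk_327 and 888 without ko_3wk_324. The interaction of genotype with week called 0 genes with edgeR, while 2038 had an unadjusted p below 0.05, DESeq2 called 237 and limma voom 1160. Without wt_5wk_213 it called 97 genes higher and 546 lower, and without wt_3wk_209 it called 2. Its smallest adjusted p among named genes was that of Rps13 (−1.07 ± 0.16, adjusted p = 0.0764), and Siglech was at −2.56 ± 0.44 (adjusted p = 0.196). Adjusted over the list alone, 19 of 20 homeostatic microglia genes, 21 of 28 lysosomal and 27 of 28 ribosomal protein genes were lower in the interaction (camera adjusted p = 2.09e-14, 4.05e-10 and 2.45e-17, adjusted p = 0.329, 0.365 and 0.342 with an estimated correlation).

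Sorted cells were first compared between populations in WT mice, as a check of the sort. OPC libraries held the lineage factors Sox10 at 440.7 ± 13.44 against 2.274 ± 0.2278 CPM in macrophages (n = 3 and 3; 7.60 ± 0.27, adjusted p = 1.98e-08) and Olig2 (7.56 ± 0.37). They also held genes of mature cells, such as the carbonic anhydrase Car2 (1812 ± 233.1 against 17.1 ± 0.6425 CPM, 6.73 ± 0.20) and Opalin (155.2 ± 35.5 against 0.5117 ± 0.1837 CPM). The lipoprotein receptor Vldlr was at 210 ± 20.43 against 0.9154 ± 0.1251 CPM. All 30 myelin genes were higher in OPC libraries, as were 21 of 24 OPC genes with 2 lower and 19 of 22 cholesterol synthesis genes with 0 lower (30, 21 and 19 adjusted over the list alone, with 0, 2 and 1 lower). Their camera adjusted p were 2.59e-19, 7.02e-07 and 1.99e-06 (adjusted p = 0.79 with an estimated correlation for each). Among the cholesterol genes, the squalene synthase Fdft1 was at 177.9 ± 46.44 against 13.51 ± 1.423 CPM (3.72 ± 0.21, adjusted p = 1.85e-07). Macrophage libraries held Ccr2 at 268.6 ± 42.38 against 2.075 ± 1.461 CPM, and the dendritic cell receptor Ccr7 at 670.5 ± 172.7 against 1.067 ± 0.3044 CPM. They held the neutrophil genes S100a8 at 1585 ± 1090 against 7.175 ± 3.492 CPM and Cd177 at 188.2 ± 107.9 against 0.4662 ± 0.6327 CPM. Of 14 MHC class II genes 13 were lower in OPC libraries (14 adjusted over the list alone; camera adjusted p = 0.00044, adjusted p = 0.79 with an estimated correlation), such as Ifi30 (−6.92 ± 0.84). The sort labelled macrophage thus carried the markers of other myeloid cells, with 11 of 11 neutrophil and 10 of 10 dendritic genes higher there than in OPC (11 and 10 adjusted over the list alone; camera adjusted p = 0.00104 and 0.00087, adjusted p = 0.79 with an estimated correlation for both). Lrp1 was lower in OPC than in macrophages (−2.78 ± 0.75, adjusted p = 0.00871). Of 17816 genes 10612 passed, 5113 higher and 5499 lower in OPC (5708 and 5627 with only these groups in the fit).

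In sorted OPC, KO and WT libraries were compared for the effect of the genotype within that population. Only 1 of 15062 genes passed, the processed pseudogene Rpl34-ps1 (ENSMUSG00000068396, chromosome 6), chosen after its values were seen. It was at 23.62 ± 7.852 CPM in KO and 0.1072 ± 0.1175 CPM in WT (n = 3 and 3; adjusted p = 0.00701), and its reads can be shared with Rpl34. Apod, a lipid carrier of myelinating cells, was at 4697 ± 1937 CPM in KO and 14320 ± 874.4 CPM in WT (−1.61 ± 0.31, adjusted p = 0.107). The pteridine reductase Qdpr was at 1334 ± 282.4 and 748.4 ± 109 CPM (0.83 ± 0.18, adjusted p = 0.107). The lineage factor Olig1 was at 0.40 ± 0.11 (adjusted p = 0.163). Of 30 myelin genes 0 passed over all genes, while 11 were higher and 2 lower adjusted over the list alone (median 0.26; camera adjusted p = 0.0424, adjusted p = 0.901 with an estimated correlation). Of 34 interferon genes 0 passed by either adjustment, with a median of −1.98 and camera adjusted p of 6.89e-12 (adjusted p = 0.79 with an estimated correlation). Members were for instance Trim30a (−3.11 ± 1.21, adjusted p = 0.34) and Ifit2, a restrictor of viral translation (85.39 ± 73.01 against 202.8 ± 25.98 CPM, −1.25 ± 0.65, adjusted p = 0.501). The interferon list mean was −0.33 log2 CPM in ko_47_OPC, 5.88 in ko_48_OPC and 0.64 in the library labelled ko_49_OPC, against 6.21 to 6.52 in WT, so ko_48_OPC stood with WT in this list. MHC class I genes had a median of −1.47 with 0 of 24 called by either adjustment (camera adjusted p = 1.07e-07, adjusted p = 0.793 with an estimated correlation). At an unadjusted p below 0.05 there were 2162 genes, and DESeq2 called 831 and limma voom 423. The edgeR count was 982 without ko_48_OPC, 5 without ko_49_OPC, 4 without wt_402_OPC, and 0 without ko_47_OPC or wt_806_OPC.

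In sorted macrophages, the lysozyme gene Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), a main product of macrophages and neutrophils, fell in KO to 23.1 ± 5.26 from 8385 ± 3500 CPM (n = 3 and 3; −8.50 ± 0.49, adjusted p = 0.00582). Every KO library was at 19.77 to 29.17 CPM and every WT library at 5284 to 12180 CPM. The call ended without ko_47_Mac or ko_49_Mac, while the fold change stayed from −8.76 to −8.14 in all 6 fits that left out 1 library. The neighbouring copy Lyz1, which can share reads with Lyz2, was at 129.8 ± 147.9 CPM in KO and 4.705 ± 0.7431 CPM in WT. Of 16047 genes 7 passed, 1 higher and 6 lower in KO. The higher one was Rpl34-ps1, at 98.29 ± 16.88 CPM in KO and 0.03629 ± 0.04153 CPM in WT (adjusted p = 0.00498, chosen after its values were seen). The other 5 that were lower were unnamed gene models. Of 20 homeostatic microglia genes 0 passed over all genes and 14 were higher adjusted over the list alone (median 1.82; camera adjusted p = 2.53e-06, adjusted p = 0.79 with an estimated correlation), such as Siglech, at 208.8 ± 129.9 against 34.18 ± 4.933 CPM (2.61 ± 0.60, adjusted p = 0.36). Of 11 neutrophil genes 0 passed by either adjustment (median 1.86; camera adjusted p = 0.000126, adjusted p = 0.79 with an estimated correlation), with the granulocyte receptor Csf3r at 739.1 ± 385.2 against 245.1 ± 29.24 CPM (1.59 ± 0.45, adjusted p = 0.36) and Ly6g at 2.44 ± 0.82 (adjusted p = 0.374). Myelin genes showed 0 calls over all genes and 18 of 30 higher adjusted over the list alone (median 1.16; camera adjusted p = 1.78e-11, adjusted p = 0.79 with an estimated correlation). Interferon and MHC class II genes had medians of −1.15 and −0.76 with 0 of 34 and 0 of 14 called by either adjustment (camera adjusted p = 4.15e-07 and 0.00123, adjusted p = 0.802 and 0.809 with an estimated correlation). Among their members were Parp14 (−1.44 ± 0.44, adjusted p = 0.368) and the co-stimulator Cd86 (−0.78 ± 0.38, adjusted p = 0.423). The scores of ko_48_Mac stood near or within the WT range, apart from ko_47_Mac and ko_49_Mac. Its homeostatic microglia score was 7.292 (WT 6.866 to 7.198, other KO 8.846 and 9.025), its neutrophil score 8.457 (WT 6.171 to 8.798, other KO 10.247 and 9.876) and its interferon score 5.952 (WT 5.547 to 6.818, other KO 3.898 and 4.776). At an unadjusted p below 0.05 there were 2043 genes, and DESeq2 called 655, of which 560 were higher and 95 lower, and limma voom 2570, 1268 higher and 1302 lower. All 12 sorted libraries in 1 fit gave 21 higher and 1 lower, so the direction of most calls rested on the fit. The count was 4246 without ko_48_Mac, 4 without wt_802_Mac, 3 without ko_47_Mac, 2 without wt_402_Mac, and 1 without wt_806_Mac or ko_49_Mac.

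**Figure D3:**
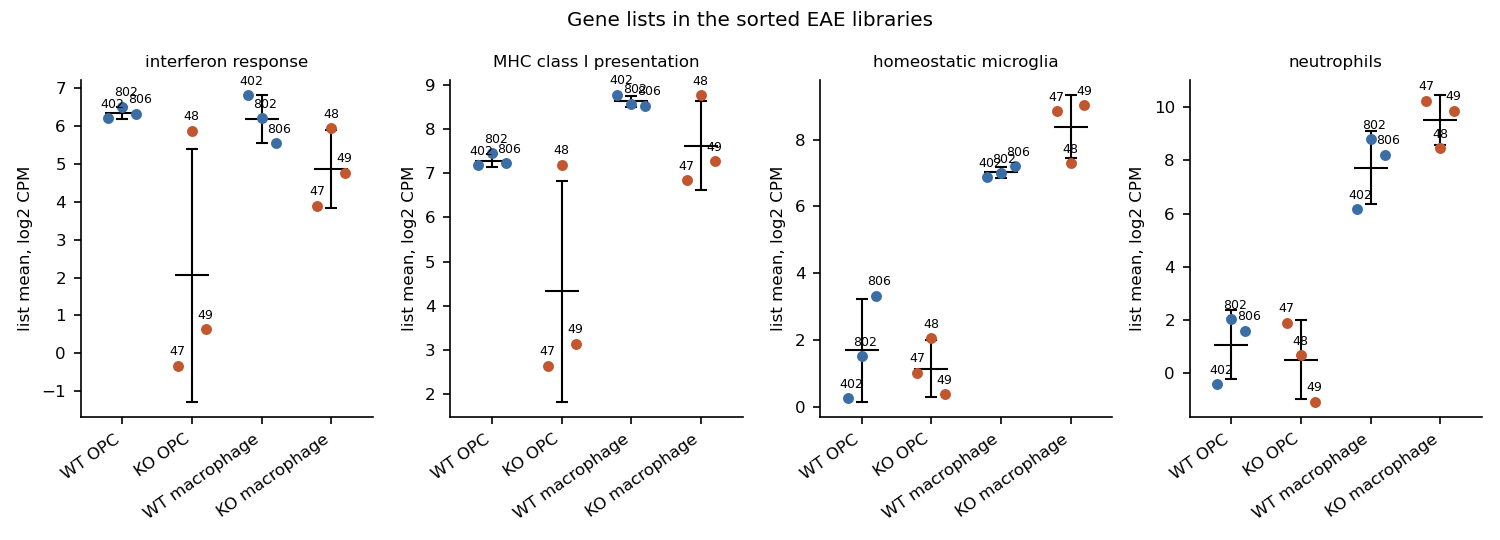
Mean log2 CPM of the interferon, MHC class I, homeostatic microglia and neutrophil lists in each sorted library, by population and genotype (WT blue, KO orange), with library numbers beside the points and black bars for mean ± SD. The library ko_48_OPC lies at 5.88 in the interferon list beside WT at 6.21 to 6.52, while ko_47_OPC lies at −0.33 and the library labelled ko_49_OPC at 0.64.

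Whether the genotype effect differed between OPC and macrophages was tested as an interaction. With edgeR it called 0 of 17816 genes, while 2167 had an unadjusted p below 0.05, DESeq2 called 481 and limma voom 372. The smallest adjusted p was that of Sash3, a lymphocyte adaptor (−4.55 ± 0.53, adjusted p = 0.0713), and Tspan3 was at 1.39 ± 0.18 (adjusted p = 0.0967). The interferon list had a median of −0.94 with 0 of 34 genes called by either adjustment (camera adjusted p = 2.53e-06, adjusted p = 0.809 with an estimated correlation). Myelin genes were lower for 17 of 30 adjusted over the list alone and for 0 over all genes (camera adjusted p = 2.24e-10, adjusted p = 0.79 with an estimated correlation). The count was 1282 without ko_48_Mac, 199 without ko_48_OPC and 3 without wt_402_OPC.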

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

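The test of sequencing depth in OPC was written before its result was seen, and the other tests of explanations and of other splits were chosen after. The Lrp1 level, total reads and list scores of 3 groups of 4 to 10 libraries were screened for a library far from the rest of its group, with 36 measures per group, and 11 of 108 sets held one, while chance gives about 1 in 20. At 3 weeks ko_3wk_321 had the lowest ependyma score of its group (3.42 against 4.39 in the nearest library, mean log2 CPM of the list) and the highest endothelial score (4.34 against 4.13), and ko_3wk_326 had the highest T cell score (−1.45 against −1.58). At 5.5 weeks ko_5_5wk_386 had the most reads of its group (38.6 against 27.46 M), and ko_5_5wk_361 the highest erythrocyte score (3.44 against −0.36). In WT, wt_5_5wk_643 was highest for MHC class I (7.23 against 6.57) and lowest for striatal neurons (0.75 against 1.62) and cholesterol synthesis (4.5 against 4.83). The B cell score was highest in wt_5_5wk_641 (−1.1 against −1.75), and wt_5_5wk_644 was lowest for dendritic cells (−0.2 against 0.38) and oxidative phosphorylation (6.5 against 6.78). All libraries stayed in every comparison.

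The genotype effect differed between 0 and 5.5 weeks for 21 genes by the interaction test. Those named were Tal1 (−4.71), Agt (−2.56), Pbx3 (−1.71), Zfhx3 (−2.55), Nfatc2 (−1.78), Cnbd2 (−1.37), Far1 (0.63), Uri1 (0.52), Barhl1 (−6.36) and Gata3 (−4.55), of which Pbx3 and Barhl1 passed in 16 of 16 fits that left out 1 library, Tal1 in 14 and Agt in 13. The others passed in 3 to 7 of the 16. The genes that are lower in this test include markers of other brain regions raised in KO at 0 weeks, and a difference in the piece dissected was not tested. Camera with the preset correlation called 17 lists for this interaction, 13 for that of 3 with 5 weeks and 11 for that of cell type, and 0 of these with an estimated correlation. Of 100 splits 10 called at least the real 21 genes, the highest other 64, so chance cannot be excluded. For the 3 to 5 week interaction the real count was 0, which all 100 splits reach by construction, so they test nothing about chance there. The highest other called 413, which points to a structure of the samples. For that of cell type the 10 splits are too few for a share under 0.05 (real 0, highest other 34).

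The share of splits with as many genes, the real one included, was under 0.05 for KO against WT at 5.5 weeks (1 of 100, real 7900, highest other 6925). That highest other split exchanged ko_5_5wk_384 and wt_5_5wk_638 and so mixed the genotypes. The share was also under 0.05 for 5.5 against 0 weeks in WT (1 of 56, real 12506, highest other 0) and in KO (2 of 56, real 4941, highest other 5446). It was under 0.05 for 5 against 3 weeks in KO as well (1 of 35, real 1461, highest other 80). For 5.5 against 0 weeks in KO, the highest other split put ko_5_5wk_361 and ko_5_5wk_386 with the untreated libraries and called more genes than the real one. Mixed groups can thus call about as many genes, so these shares alone do not exclude chance or a structure of the samples. At 3 weeks 2 of 35 splits called as many genes as KO against WT (real 12, highest other 15), so chance cannot be excluded. The splits are too few for a share under 0.05, at 10 each, for KO against WT at 0 weeks (2 splits as large, real 59, highest other 143) and at 5 weeks (1, real 922, highest other 0). The same holds for 5 against 3 weeks in WT (1, real 4611, highest other 0), OPC against macrophages in WT (1, real 10612, highest other 0), and KO against WT in OPC (3, real 1, highest other 4) and in macrophages (1, real 7, highest other 0). At 0 weeks the highest other split exchanged ko_0wk_467, of 15.14 M reads, with wt_0wk_852.

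The first pattern weighed is the interferon list in sorted OPC, with a score of 6.21 to 6.52 in WT, 5.88 in ko_48_OPC, 0.64 in ko_49_OPC and −0.33 in ko_47_OPC. After all 12 libraries were thinned to 11.97 M reads, the gap between the lowest WT and the lowest KO library was 6.59 (6.54 before), which argues against depth, and in 0 of 2 populations did the KO library with the most Lrp1 left in the cells lie closest to WT. Leukocyte RNA in the WT OPC sort is argued against by a median of 0.1 (SD 2.02, 34 genes) for interferon genes in WT OPC over macrophages and of −6.4 (SD 1.98, 48 genes of the monocyte and macrophage, T cell and MHC class II lists) for leukocyte genes, 6.5 apart. Ifit3 was at 491.8 ± 6.338 CPM in WT OPC and 29.67 ± 18.99 in WT macrophages, whereas Cd74 was at 72.34 ± 70.39 and 7918 ± 1509 and Ptprc at 14.77 ± 7.981 and 955.2 ± 91.44 CPM. What stays open is the state of the animal, which may be shared by libraries of 1 number (lowest correlation over genes 0.11 among KO pairs, genes not being independent replicates), and an effect of genotype present in part of the KO mice. Such an effect would not follow the Lrp1 left in these libraries, at 14.73 (ko_47_OPC), 18.78 (ko_48_OPC) and 159.4 CPM (ko_49_OPC). The library with a score beside WT had lost Lrp1, and ko_49_OPC with a low score had kept it.

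A second pattern is the near absence of Lyz2 from the KO macrophage libraries, at 23.1 ± 5.26 against 8385 ± 3500 CPM. Fewer macrophages in the sort are argued against by the 18 genes of the monocyte and macrophage list, which does not hold Lyz2. Their median was −0.28 (SD 1.64), and microglia also express some of them. Reads given to the near-identical Lyz1 do not account for the fall, since the sum of both genes was 152.9 ± 153.1 CPM in KO and 8390 ± 3501 CPM in WT, a log2 ratio of −5.78. What stays open is an altered Lyz2 allele in these mice, such as the Cre insertion at this locus used to delete genes in myeloid cells, which may leave its neighbours alone (18 genes tested within 1 Mb, median 0.08, SD 0.77, from −1.72 to 1.78, 0 called). Whether these mice carry such an allele is not given in the sources used here, and Lyz2 lies 10.3 Mb from Lrp1 on the same chromosome, while KO cuprizone tissue at 5.5 weeks held Lyz2 at 546.6 ± 234.3 CPM.

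The third pattern is the 7900 genes called between KO and WT at 5.5 weeks. Scaling of the KO libraries by one wrong factor is argued against by 7794 genes, the fewest called at any factor from −1 to 1 log2 units, though how many rose or fell does rest on it (3680 and 4220 as scaled, 2269 and 5525 with KO lowered by 0.1, 5270 and 3202 with KO raised by 0.1). The microglial content of the tissue stays open, since slopes on the microglia list within each group predicted the fold changes of 7880 called genes outside that list with a correlation over genes of 0.88 and the same sign in 98.1%, genes not being independent replicates. With that list as a covariate the median absolute fold change went from 0.68 (median SE 0.19) to 0.18 (median SE 0.22), so the calls ended mainly because the differences shrank, and Lrp1 went to 0.26 ± 0.34 (adjusted p = 0.92). More neuronal tissue in the KO samples stays open as well, since a KO minus WT difference of −3.06 in the microglia list relative to the myelin list (KO −0.51 ± 0.9, WT 2.55 ± 1.37, exact permutation p = 0.00794, two-sided, n = 5 and 5) could come from unlesioned tissue with myelin of its own, from a smaller lesion or from fewer or less activated microglia, and no value here parts them.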

How the results depend on the processing

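The removal of both libraries under 20 M reads and the microglia covariate were chosen after seeing the data, the other alternatives before. The WT comparison of 5.5 with 0 weeks (12506 genes) and that of OPC with macrophages (10612) stayed within 1.5 times their count under every alternative run on them, including leaving out each library (11477 to 12322 and 9151 to 9819). DESeq2 size factors in place of TMM kept all 14 counts within 1.5 times. The median fold change of all genes between OPC and macrophages was −0.072 with TMM, −0.103 with DESeq2 size factors, −0.168 with the replicate block and −0.37 with no low-count filter. The DESeq2 test called 159 genes between KO and WT at 0 weeks (59 by edgeR), 31 at 3 weeks (12), 1437 at 5 weeks (922), 831 in OPC (1) and 655 in macrophages (7). For the interactions it called 2460 from 0 to 5.5 weeks (21), 237 from 3 to 5 weeks (0) and 481 between populations (0). By limma voom there were 215 at 0 weeks, 3919 at 5 weeks, 12253 at 5.5 weeks (7900), 423 in OPC, 2570 in macrophages, 9312 from 0 to 5.5 weeks in KO (4941), 2877 from 3 to 5 weeks in KO (1461), and 7270, 1160 and 372 for the interactions in that order. With no low-count filter the counts were 21 at 3 weeks, 517 in OPC, 14 in macrophages, 6 for the 3 to 5 week interaction and 1 for that of population. Under the transcript length offset they were 464 at 5 weeks, 928 from 3 to 5 weeks in KO, 13 for the 0 to 5.5 week interaction and 2 for the 3 to 5 week one. All 12 sorted libraries in 1 fit gave 6 in OPC and 22 in macrophages, and only the groups compared in the fit gave 13 at 5 weeks. Without both libraries under 20 M reads there were 33 at 0 weeks, 2675 from 0 to 5.5 weeks in KO and 1 for that interaction, with fewer libraries by construction. With the microglia covariate 7 genes were called at 5 weeks and 16 at 5.5 weeks, since by construction it takes up what goes with that list. Camera called lists in 226 cases, 0 with an estimated correlation. Fry, which asks a different question, called 130, but 0 for KO against WT at 0 and 3 weeks and in sorted cells. For the other changes the cause was not tested. Leaving out each library in turn gave 37 to 64 genes at 0 weeks (37 without ko_0wk_466 or wt_0wk_854, 38 without ko_0wk_468) and 7 (without wt_3wk_211) to 11 at 3 weeks. At 5 weeks it gave 9 (without ko_5wk_327) to 2256 (wt_5wk_213), with 16 without ko_5wk_298, 23 without wt_5wk_212, 95 without wt_5wk_214 and 345 without ko_5wk_320. At 5.5 weeks the range was 5234 (without ko_5_5wk_386) to 9141. From 0 to 5.5 weeks in KO it was 2613 (without ko_0wk_467) to 5700, with 2669 without ko_0wk_466, 2854 without ko_0wk_468 and 3289 without ko_5_5wk_383. The interaction ranged from 6 (without wt_0wk_854) to 3435 (ko_5_5wk_384), with 591 without wt_5_5wk_643, 69 without wt_0wk_852, 12 without ko_0wk_468, 10 without wt_5_5wk_640, 9 without ko_0wk_466 or ko_5_5wk_386, and 7 without ko_0wk_467, wt_0wk_853, ko_5_5wk_383 or ko_5_5wk_385. From 3 to 5 weeks the range was 3018 (without wt_5wk_212) to 5145 in WT and 593 (without ko_5wk_320) to 1546 in KO, with 680 without ko_5wk_298, 876 without ko_5wk_327 and 888 without ko_3wk_324. That interaction ranged from 0 to 6.4e2 (97 higher and 546 lower, without wt_5wk_213), with 2 without wt_3wk_209. In OPC the range was 0 (without ko_47_OPC or wt_806_OPC) to 982 (ko_48_OPC), with 5 without ko_49_OPC and 4 without wt_402_OPC. In macrophages it was 1 (without wt_806_Mac or ko_49_Mac) to 4246 (ko_48_Mac), with 2, 3 and 4 without wt_402_Mac, ko_47_Mac and wt_802_Mac. The population interaction ranged from 0 to 1282 (without ko_48_Mac), with 199 without ko_48_OPC and 3 without wt_402_OPC. Lrp1 differed at 3 weeks by −1.12 under the length offset (adjusted p = 0.194) and by −1.3 to −1.13 without single libraries. With the covariate it differed by −1.49 at 5 weeks (adjusted p = 0.215) and was reversed at 0.26 at 5.5 weeks (adjusted p = 0.92). In macrophages it passed by DESeq2 (−1.32) and voom (−1.25), with −1.4 to −1.24 without single libraries, and in OPC these gave −3.52 to −1.12. Other genes reversed by the covariate were Trem2 (0.15) and Hexa (0.02) at 5 weeks and Fcrls (0.1), Slc17a7 (−0.21), Gad1 (−0.29), Hmgcs1 (−0.04), Npc2 (0.41), Serpine2 (0.14) and Fn1 (0.32) at 5.5 weeks, all with adjusted p above 0.05. Over all settings, the 149 gene values named in the text kept direction and side of the threshold in 1890 of 2200 cases, lost the call in 259, gained it in 42 and reversed in 9. The covariate accounts for 29 losses and those 9. DESeq2 gave no adjusted p for Lrp1 in OPC. The library numbers were not used as pairs in the main design, since the labels do not pair them. Correlations over genes for the same number were all positive (WT 0.05, 0.07 and 0.1, KO 0.13, 0.11 and 0.12). They were −0.07 to 0 for different numbers, and 6 of 6 macrophage libraries correlated best with their own number, which comes from the data and not the design. Among genes picked after their values were seen, Gm13456 was high only in wt_402_OPC and wt_402_Mac (415 and 3103 reads). BC002163 was found only in wt_806_OPC and wt_806_Mac (184 and 107 reads), and Ttr was high only in ko_49_OPC and ko_49_Mac (418 and 1742 reads). Libraries of 1 number may thus share an animal, while the main fit of all 12 treats them as independent. As a replicate block the number gave 9624 genes between WT OPC and macrophages and 0 for the interaction. Depth was 3.34 to 9.57 M reads in the later batch, 15.14 to 38.6 M in the earlier one and 11.97 to 43.87 M in the sorted cells, which limits what low-count genes can show in each.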

Other observations

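The gene lists below were fixed before the data were examined, and which of them to describe was chosen after their values were seen. At 5.5 weeks in WT, 13 of 15 genes of LXR signalling and lipid efflux were higher than in untreated tissue and 1 was lower, also adjusted over the list alone (camera adjusted p = 0.000535, adjusted p = 0.573 with an estimated correlation). Abca1, which exports cholesterol from lipid-laden cells, rose to 615.3 ± 109.6 from 40.29 ± 6.664 CPM (n = 5 and 3; 3.93 ± 0.41, adjusted p = 1.34e-05), and the lysosomal cholesterol carrier Npc2 to 992 ± 367.4 from 51.4 ± 1.821 CPM (4.27 ± 0.54). Of 21 genes for ligands of Lrp1, 16 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.000498, adjusted p = 0.573 with an estimated correlation). The protease inhibitor A2m rose to 273.3 ± 61.91 from 2.182 ± 0.4144 CPM (6.96 ± 0.56, adjusted p = 3.59e-06) and Apoe to 26540 ± 3582 from 987.7 ± 130.9 CPM (4.75 ± 0.52).

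Between KO and WT at 5.5 weeks, 0 of 15 lipid efflux genes rose and 10 fell (10 adjusted over the list alone; camera adjusted p = 0.00155, adjusted p = 0.574 with an estimated correlation), with Npc2 at 328.5 ± 242.1 and 992 ± 367.4 CPM (n = 5 and 5; −1.59 ± 0.39, adjusted p = 0.00816). Of the Lrp1 ligands 3 rose and 8 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.0328, adjusted p = 0.682 with an estimated correlation). Among those that fell were fibronectin, Fn1, at 218.5 ± 222.7 and 1593 ± 1121 CPM (−2.87 ± 0.65, adjusted p = 0.00649), and Serpine2, at 350.8 ± 136.2 and 879.5 ± 369.1 CPM (−1.33 ± 0.27, adjusted p = 0.00476). The LDL receptor family was mixed, with 6 rises and 4 falls among 14 genes by either adjustment, and Lrpap1, the chaperone of Lrp1, fell to 159.8 ± 30.55 from 296.7 ± 86.74 CPM (−0.89 ± 0.17, adjusted p = 0.00397). Genes of the integrated stress response moved both ways, with 2 rises and 12 falls among 23 (2 and 13 adjusted over the list alone; camera adjusted p = 0.00886, adjusted p = 0.573 with an estimated correlation). Of 14 T cell genes 8 rose and 1 fell from untreated levels in WT (9 and 1 adjusted over the list alone), and 9 rose and 0 fell in KO (10 and 0). Between KO and WT 0 of them rose and 2 fell by either adjustment. With the microglia list mean as a covariate, Npc2 (0.41 ± 0.19), Fn1 (0.32 ± 0.39), Serpine2 (0.14 ± 0.19) and Lrpap1 (−0.08 ± 0.19) no longer differed past the threshold (adjusted p from 0.62 to 0.965).

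Rpl34-ps1, BC002163, Gm13456 and Gm3608 separated all KO from all WT tissue libraries within each week, and these and Gabra2 were chosen after their values were seen. Rpl34-ps1, a ribosomal pseudogene, was at 23.86 ± 1.561 CPM in KO and 0.02362 ± 0.0409 CPM in WT at 0 weeks (n = 3 and 3) and at 40.24 ± 10.37 and 0.07866 ± 0.1331 CPM at 5.5 weeks (n = 5 and 5). It was at 61.13 ± 31.16 CPM in KO and 0 CPM in WT at 3 weeks, and from 0.7112 to 117.1 CPM in KO at 5 weeks. BC002163 was at 0 CPM in KO and 13.54 ± 4.325 CPM in WT at 0 weeks, Gm13456 at 0.7253 ± 0.3078 and 20.01 ± 3.751 CPM, and Gm3608 at 0.3437 ± 0.1379 and 12.67 ± 1.198 CPM. In the sorted cells Gm3608 was at 0.6417 ± 1.112 CPM in KO OPC and 23.07 ± 0.3916 CPM in WT OPC, whereas Gm13456 was at 33.59 CPM in wt_402_OPC, 93.51 CPM in wt_402_Mac and at most 1.006 CPM in the other sorted libraries. Gabra2, a protein-coding gene, was also higher in KO at 0 weeks. At 3 weeks its KO range of 40.59 to 153.5 CPM overlapped the WT range of 47.27 to 53.51 CPM. These genes lie on chromosomes 1, 2, 5, 6 and 16, and Lrp1 on 10. Genetic background was not separated from genotype, and the source of these differences was not analysed.

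In ko_47_Mac, ko_49_Mac and ko_48_Mac the MHC class II score was 5.96, 6.75 and 9.3 (WT 8.71 to 8.96). The neutrophil score was 9.53 ± 0.94 in KO and 7.73 ± 1.38 in WT macrophages (mean log2 CPM, n = 3 and 3). An exact permutation p below 0.1 cannot come from 3 libraries against 3.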
